A study of Mus musculus with 15 samples.

How the data were processed

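Gene expression was measured by paired-end sequencing (read length 150 bases) of total RNA from 15 mouse brain samples: 3 of astrocytes, 3 each of induced cells on days 4, 8 and 16, and 3 of primary neurons. The authors deposited 1 table of FPKM values for all samples, with 24346 gene symbols, and per the submitters' processing notes the genome was mm10 (GRCm38). The aligner, the quantifier and the annotation were not given in the sources used here. All 15 value columns matched a sample title, no symbol was repeated, and 4866 genes were listed at 0 in every library. Of the symbols, 24228 were matched to a gene annotation, 23142 of them by current symbol, to give chromosome positions. Groups, comparisons, tests, gene lists and most alternatives were fixed before the data were examined. The labels do not say whether the samples of a group come from separate cultures, so p-values measure only the spread between these samples, which may be technical.

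Read counts were not used here, and the depth was read from the whole-number steps of low FPKM values. Among 2865 genes with low values (up to 0.5 FPKM), 55.4 to 78.9% of the ratios between library steps fell within 0.02 log2 of whole-number ratios, against 10.8% expected. Relative depth ran from 0.71 to 2.04, with primary neurons at 1.69 to 2.04, and the absolute depth could not be read from the values. FPKM totals ran from 548309 to 787080 per library, and 11861 to 12907 genes per library reached 1 FPKM. The median standard error of a log2 change was 0.201.

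Values were transformed as log2(FPKM + 1). A gene was tested when it reached 1 FPKM in at least 3 of the 15 libraries, which left 13983 genes. limma 3.58.1 in R 4.3.3 fitted all 15 libraries in 1 group-means model with 10 residual degrees of freedom, with moderated t-tests and a trend of the variance on the mean. P-values were adjusted by Benjamini-Hochberg per comparison, and a gene was called at an adjusted p below 0.05 and an absolute log2 change of at least 1. Comparisons were D4, D8, D16 and PN against D0, D16 against PN, D8 against D4 and D16 against D8. Gene lists (29 lists, 650 symbols, 577 tested) were tested with camera at a preset correlation of 0.01 and, as an alternative, with a correlation estimated per list. Lists needed at least 5 tested genes.

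Genes were named by a fixed rule: the 6 called genes with the largest change in each direction that did not overlap between groups and reached 5 FPKM in the higher group, up to 4 called members of each list, 4 transient genes each way, and a fixed panel of markers. With 3 libraries against 3, non-overlap alone happens in 10% of unchanged genes. The overlap of the D16 and PN changes was compared with the product of the 2 counts and with 50 simulations of unchanged groups sharing D0. Position between D0 and PN was the mean change of the genes called between PN and D0, as a percent of the PN change, and was tested by exact permutation of libraries.

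The test of D16 against D0 was checked on simulated data. Over 5 simulations, a planted 2-fold change was called in 26.8% of genes, 3-fold in 87.6%, 4-fold in 96.4% and 8-fold in 98.8%. Each fold was planted in 250 gene tests over the 5 simulations, far fewer than the 4935 genes called between D16 and D0. Changes were planted only in genes above about 5 FPKM at D0, so the rates do not cover genes with low values at D0. They were not split by expression level and may not hold where many genes change. Of 68765 unchanged gene tests, 23 were called (0.0335%). A shifted gene list was called in 5 of 5 simulations and an unshifted list in 0 of 5. Simulated genes varied independently, whereas the correlations estimated within the real lists ran from 0.0503 to 0.630. The list check therefore does not cover lists whose genes vary together.

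Replicate numbers were checked as pairs by correlating the deviations of each library from its group mean. Between D4 and D8 all 3 same-number pairs correlated at 0.329 to 0.454, against -0.497 to 0.114 for the other pairs. The numbers thus link those samples, whether by culture, depth or processing. Between the other groups compared, same-number pairs correlated at -0.135 to 0.275, with no comparison above 0.1 in all 3 pairs. The model without pairs was kept as fixed, and a replicate block was run as an alternative.

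Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, rescaling to an equal total, quantile normalization, a replicate block, a fit of the 2 groups compared, leaving out each library in turn, and no minimum on the change. A fit without D16 replicate 2 and PN replicate 3 was chosen after seeing the data. Figures and table summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.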

Results

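RNA sequencing compared mouse brain cells of the C57BL/6 strain in 5 groups of 3 libraries. The groups were astrocytes (D0), cells labelled as chemically induced neurons on days 4, 8 and 16 (D4, D8 and D16), and primary neurons (PN). By D16 the astrocyte filament gene Gfap (chromosome 11, start 102887336, end 102897200) had gone from 560 ± 239 to 4.22 ± 6.68 FPKM (mean ± SD, n = 3 per group). The synaptic vesicle fusion gene Snap25 (chromosome 2, start 136713439, end 136782428) had gone from 0.183 ± 0.289 to 172 ± 39.2 FPKM, against 195 ± 83.4 FPKM in PN. The migrating-neuron microtubule gene Dcx (chromosome X, start 143855842, end 143933396) stayed at 0.318 ± 0.103 FPKM at D16 and stood at 132 ± 18.8 FPKM in PN. Libraries of one group correlated at 0.966 to 0.987 (Pearson, log2 of FPKM + 1). D16 correlated at 0.971 with D8, 0.779 with PN and 0.750 with D0 on average, and D0 and PN at 0.685. Changes below are on the log2(FPKM + 1) scale with standard errors, which understates the change of genes with low values. A gene is called at an adjusted p below 0.05 and a change of at least 1.

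**Figure D1:**
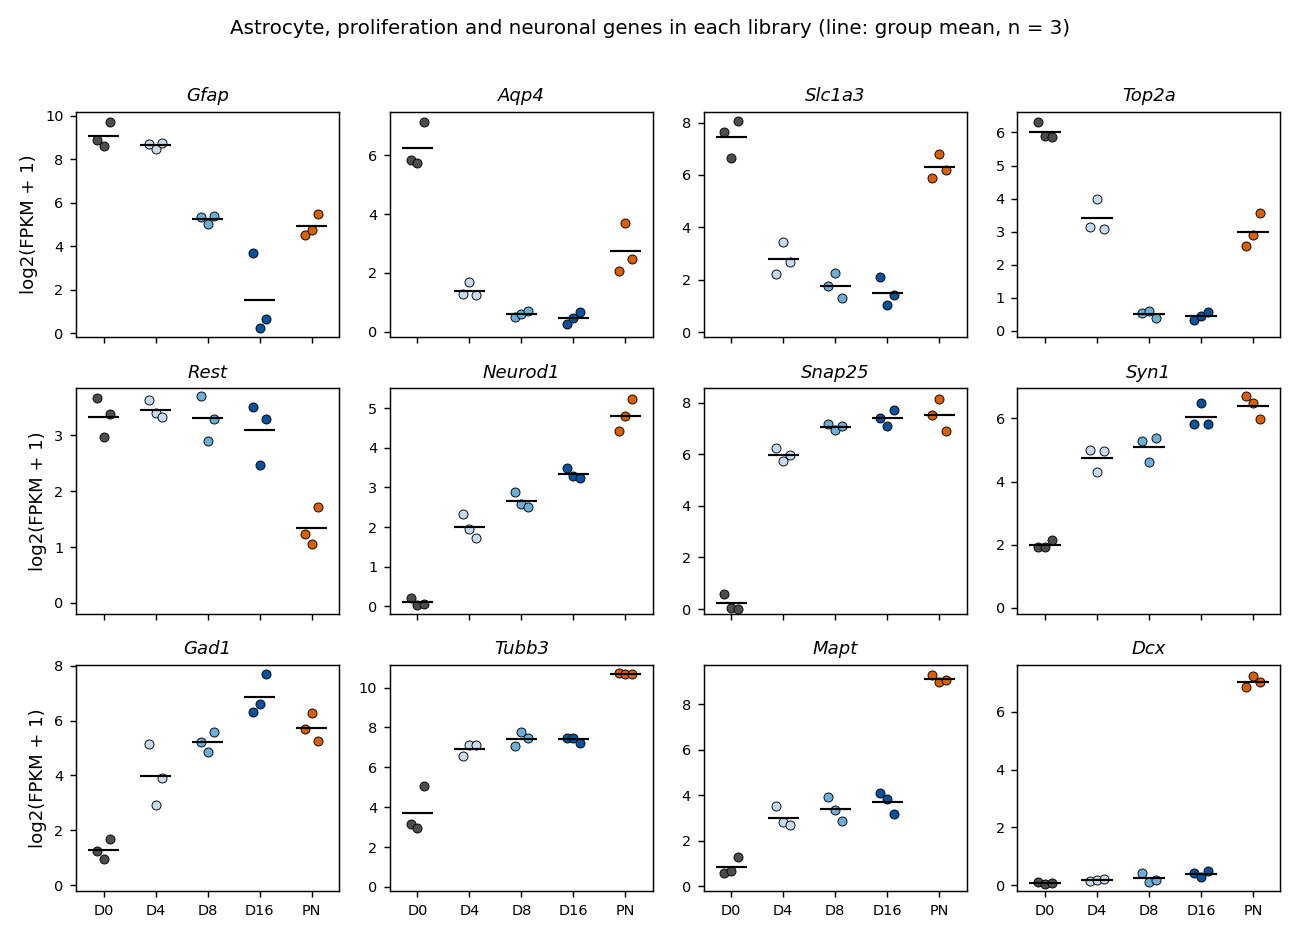
Astrocyte, neuronal, transmitter and cell cycle genes in each of the 15 libraries. Points are single libraries and lines are group means, on a log2(FPKM + 1) axis, for astrocytes (D0), induced cells on days 4, 8 and 16, and primary neurons (PN).

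Between D0 and D4, 1896 genes rose and 1991 fell of 13983 tested. The largest rises included the calcitonin peptide gene Calca (chromosome 7, start 114625981, end 114636910; 3.34 ± 1.76 to 2791 ± 2030 FPKM, log2 change 9.12 ± 0.65, adjusted p = 4.3e-08). The secreted lipocalin gene Lcn2 followed (1.35 ± 1.06 to 451 ± 365 FPKM, 7.36 ± 0.73). Cryba2, a crystallin gene (6.87 ± 0.39), Calcb (6.73 ± 0.53) and the galanin gene Gal (6.42 ± 0.56) also rose. Calca and Calcb are close paralogs, so reads may be shared between them. The largest falls were in smooth muscle actin Acta2 (chromosome 19, start 34240336, end 34255585; 1950 ± 1600 to 3.34 ± 2.61 FPKM, -8.66 ± 0.95) and Tagln (2246 ± 1550 to 9.46 ± 6.7 FPKM, -7.72 ± 0.94). They were followed by the growth factor binding gene Igfbp5 (-6.14 ± 0.53), the matrix proteoglycan gene Prelp (-5.92 ± 0.23), S100a4 (-5.86 ± 0.36) and the radial glia lipid-binding gene Fabp7 (1499 ± 326 to 30.04 ± 13.9 FPKM, -5.67 ± 0.54). Gfap was at 398 ± 42.6 FPKM at D4 and was not called (-0.41 ± 0.62, adjusted p = 0.60).

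Several neuronal groups were already higher at D4. Of 30 presynaptic genes 20 were higher, 1 lower and 9 not called, with Snap25 at 62.9 and Syp at 77.2 FPKM (list called; adjusted p = 0.264 with an estimated correlation). Of 35 pan-neuronal genes 22 were higher, 4 lower and 9 not called, among them Crmp1 (2.20 to 65.6 FPKM) and Nefl (4.90 to 90.4 FPKM; list called, adjusted p = 0.264 with an estimated correlation). Neuropeptide and secretory granule genes were higher in 18 of 21, none lower and 3 not called, with Vgf from 58.6 to 3029 FPKM (list called; adjusted p = 0.259 with an estimated correlation). GABAergic genes were higher in 12 of 17, 1 lower and 4 not called (list called; adjusted p = 0.264 with an estimated correlation). Proneural transcription factors were higher in 11 of 24, 1 lower and 12 not called, with Scrt1 from 0.0107 to 20.7 FPKM (list called; adjusted p = 0.259 with an estimated correlation). Channel genes were higher in 8 of 22, 1 lower and 13 not called, and postsynaptic genes higher in 6 of 28, 4 lower and 18 not called. Both lists were called (adjusted p = 0.573 and 0.640 with an estimated correlation). Glutamatergic genes were higher in 3 of 12, 1 lower and 8 not called, and the list was not called (adjusted p = 0.157). All 20 actin and SRF target genes were lower (list called; adjusted p = 0.266 with an estimated correlation). Cell cycle genes were lower in 30 of 33 with 3 not called, including Plk1 (52.8 to 3.25 FPKM; list called, adjusted p = 0.264 with an estimated correlation). Astrocyte identity genes were lower in 17 of 27, with 2 higher and 8 not called (3 higher and 17 lower adjusted over the list alone). The glutamate transporter Slc1a3 went from 189 to 6.33 FPKM (list called; adjusted p = 0.465 with an estimated correlation). The ependymal list, with Foxj1 at 113 FPKM at D0, had 7 of 11 genes lower, 1 higher and 3 not called (list called; adjusted p = 0.264 with an estimated correlation). In the other 28 lists the counts adjusted over the list alone were unchanged. No list was called with an estimated correlation (lowest adjusted p = 0.259).

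Some groups at D4 followed no single direction. The stress-response list had 6 of 22 genes higher, 1 lower and 15 not called, with Atf3 (5.61 to 43.5 FPKM) and Ddit3 (24.0 to 135 FPKM) higher. Wnt targets had 8 of 14 higher, 4 lower and 2 not called, with Sp5 from 0.566 to 32.5 FPKM. Microglia and macrophage genes had 3 of 10 higher, 6 lower and 1 not called. The lysosomal glycoprotein gene Cd68 went from 17.5 to 296 FPKM while Tyrobp went from 5.39 to a listed 0. None of the 32 oxidative phosphorylation genes was called. The adjusted list p-values for the 4 groups were 0.364, 0.0657, 0.878 and 0.878.

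At D8, 2164 genes were higher and 2360 lower than at D0. Gal had the largest rise (0.606 ± 0.822 to 574 ± 234 FPKM, 8.53 ± 0.56, adjusted p = 9.5e-09), followed by Calca (1054 ± 686 FPKM, 7.83 ± 0.65). Other large rises were in the secretory granule gene Resp18 (149 ± 27.2 FPKM, 7.13 ± 0.37), the tumour necrosis factor receptor family gene Cd40 (203 ± 172 FPKM, 6.94 ± 0.47) and Cryba2 (6.90 ± 0.39). The falls were led by Acta2 (0.249 ± 0.322 FPKM left, -10.32 ± 0.95), S100a4 (-9.45 ± 0.36), Tagln (-9.14 ± 0.94), Igfbp5 (-6.93 ± 0.53) and the astrocyte membrane gene Mlc1 (218 ± 101 to 0.861 ± 0.437 FPKM, -6.81 ± 0.46). Snora81, a small nucleolar RNA listed at 0 in all D8 libraries, also qualified (-9.65 ± 2.53), but its values scattered from 0 to 3222 FPKM within D16. Gfap was down to 37.1 ± 5.22 FPKM (-3.81 ± 0.62).

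At D8 the presynaptic list had 24 of 30 genes higher, 1 lower and 5 not called, and the pan-neuronal list 26 of 35 higher, 2 lower and 7 not called (lists called; adjusted p = 0.180 and 0.141 with an estimated correlation). Cplx1 went from 0.335 to 86.0 FPKM and Stmn4 from 0.734 to 124 FPKM. Neuropeptide genes were higher in 19 of 21 with 2 not called, among them Nts (listed at 0 at D0, 84.3 FPKM at D8; list called, adjusted p = 0.141 with an estimated correlation). Lysosome genes were higher in 13 of 21, 1 lower and 7 not called, including the cathepsin gene Ctsb (196 to 936 FPKM; list called, adjusted p = 0.141 with an estimated correlation). The cell cycle list was lower in 31 of 33 with 2 not called, including Top2a (64.7 to 0.432 FPKM; list called, adjusted p = 0.141 with an estimated correlation). Neural progenitor genes were lower in 14 of 19, 1 higher and 4 not called, and the 1 that rose was Hopx (10.6 to 284 FPKM; list called, adjusted p = 0.326 with an estimated correlation). List counts adjusted over the list alone were the same for all 29 lists.

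At D16, 2319 genes were higher and 2616 lower than in astrocytes. The interneuron peptide gene Vip (chromosome 10, start 5639193, end 5647617) rose most, from 0.204 ± 0.245 to 697 ± 545 FPKM (8.64 ± 0.69, adjusted p = 5.4e-08). Other large rises were in Resp18 (223 ± 123 FPKM, 7.52 ± 0.37), Snap25 (7.19 ± 0.27, adjusted p = 2.7e-11) and Cd40 (188 ± 91.2 FPKM, 7.09 ± 0.47). The posterior homeobox gene Hoxb9 (chromosome 11, start 96271330, end 96276595) was listed at 0 at D0 and at 166 ± 137 FPKM at D16 (6.997 ± 0.44). The largest falls were Acta2 (0.0685 ± 0.119 FPKM left, -10.52 ± 0.95), Tagln (-9.81 ± 0.94), S100a4 (-9.45 ± 0.36) and Gfap (-7.53 ± 0.62, adjusted p = 8.0e-08). They were followed by the matrix gene Fmod (196 ± 121 to 0.0112 ± 0.0193 FPKM, -7.44 ± 0.63) and Myl9 (757 ± 479 to 3.03 ± 1.24 FPKM, -7.42 ± 0.64). Single libraries differed several-fold in some of these genes. Vip was at 112, 789 and 1190 FPKM and Hoxb9 at 46.6, 138 and 315 FPKM in D16 replicates 1, 2 and 3. Gfap was at 11.9, 0.161 and 0.573 FPKM in the same order.

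Of 30 presynaptic genes 26 were higher at D16, 1 lower (Cplx2) and 3 not called, with Syp from 2.28 to 196 FPKM and Syt4 from 0.446 to 96.5 FPKM (mean change 3.01; list called, adjusted p = 0.154 with an estimated correlation). Of 35 pan-neuronal genes 26 were higher, 2 lower (Dpysl3 and Thy1) and 7 not called, with Stmn4 from 0.734 to 192 FPKM and Ina from 0.307 to 78.9 FPKM (list called; adjusted p = 0.154 with an estimated correlation). The neuropeptide list was higher in 17 of 21 with 4 not called, led by Gal at 228 FPKM and Nts at 125 FPKM (list called; adjusted p = 0.154 with an estimated correlation). GABAergic genes were higher in 12 of 17, 1 lower and 4 not called. The GABA-synthesis gene Gad1 (chromosome 2, start 70561303, end 70602014) went from 1.51 to 126 FPKM and the vesicular GABA transporter Slc32a1 from a listed 0 to 70.8 FPKM (list called; adjusted p = 0.158 with an estimated correlation). Of 16 listed monoaminergic and cholinergic genes only 8 passed the filter, of which 7 were higher and 1 not called. Among them was the acetylcholine transporter Slc18a3 (0.0270 to 16.5 FPKM). The list was called (adjusted p = 0.154 with an estimated correlation). The listed gene Th did not pass (0.276 FPKM at D0, 0.0386 FPKM at D16). Mean log2 levels of the 8 were 0.17 to 0.369 in D0 libraries and 0.401 to 0.65 in PN libraries. The filter may therefore favour genes that rose in the induced cells. Glutamatergic genes were higher in only 4 of 12, 1 lower (Fezf2) and 7 not called, with the vesicular glutamate transporter Slc17a7 from 0.114 to 24.3 FPKM (list called; adjusted p = 0.339 with an estimated correlation).

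Channels were higher in 14 of 22 genes, 1 lower and 7 not called, with Cacna1b from 0.102 to 19.5 FPKM (list called; adjusted p = 0.353 with an estimated correlation). Postsynaptic genes were higher in 14 of 28, 3 lower (Camk2a, Gria1 and Gria3) and 11 not called, with Grin1 from 0.216 to 50.8 FPKM (list called; adjusted p = 0.360 with an estimated correlation). Proneural factors were higher in 13 of 24, 1 lower and 10 not called. Neurod1 went from 0.0770 to 9.17 FPKM (list called; adjusted p = 0.154 with an estimated correlation). Immediate-early genes were higher in 10 of 24, 3 lower and 11 not called, with Egr1 from 15.8 to 156 FPKM (list called; adjusted p = 0.479 with an estimated correlation). Lysosome genes were higher in 11 of 21, 1 lower (Wipi1) and 9 not called, with Gpnmb from 19.9 ± 17.2 to 446 ± 386 FPKM (list called; adjusted p = 0.154 with an estimated correlation). The neuronal-gene repressor Rest was not called at D16 (9.32 ± 2.46 to 7.94 ± 3.02 FPKM, adjusted p = 0.47).

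Among the falling groups at D16, cell cycle genes were lower in 30 of 33 and not called in 3 (Pcna, Tyms and E2f1), with Ccnb1 from 72.1 to 0.141 FPKM (list called; adjusted p = 0.154 with an estimated correlation). All 20 actin and SRF target genes were lower (mean change -4.62; list called, adjusted p = 0.227 with an estimated correlation). Astrocyte identity genes were lower in 19 of 27 and not called in 5, with Aqp4 from 83.2 to 0.391 FPKM, while Slc7a10, Ntsr2 and Cbs were higher (list called; adjusted p = 0.290 with an estimated correlation). Reactive astrocyte genes were lower in 17 of 31, 4 higher and 10 not called. Emp1 went from 270 to 3.59 FPKM, and Lcn2, H2-D1, Srgn and Fkbp5 were higher (list called; adjusted p = 0.339 with an estimated correlation). Progenitor genes were lower in 15 of 19, 1 higher and 3 not called, matrix genes in 12 of 15, 1 higher (Fbln1) and 2 not called, and ependymal genes in 7 of 11 with 4 not called (lists called; adjusted p = 0.258, 0.258 and 0.158 with an estimated correlation). Fabp7 was left at 29.5 FPKM, Sparc went from 1362 to 14.4 FPKM, and Foxj1 was left at 0.412 FPKM. No call was made for the oligodendrocyte (4 of 11 higher, 3 lower, 4 not called), microglia (3 of 10 higher, 6 lower, 1 not called), endothelial (1 of 6 higher, 1 lower, 4 not called), Wnt (7 of 14 higher, 4 lower, 3 not called) and Notch (6 of 12 lower, 6 not called) lists. Nor was one made for sterol synthesis (1 of 24 higher, 1 lower, 22 not called), glycolysis (2 of 21 higher, 4 lower, 15 not called), oxidative phosphorylation (0 of 32 called), p53 targets (3 of 17 higher, 3 lower, 11 not called), stress responses (4 of 22 higher, 2 lower, 16 not called) or interferon-stimulated genes (9 of 18 lower, 9 not called). List counts adjusted over the list alone matched for all 29 lists.

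**Figure D2:**
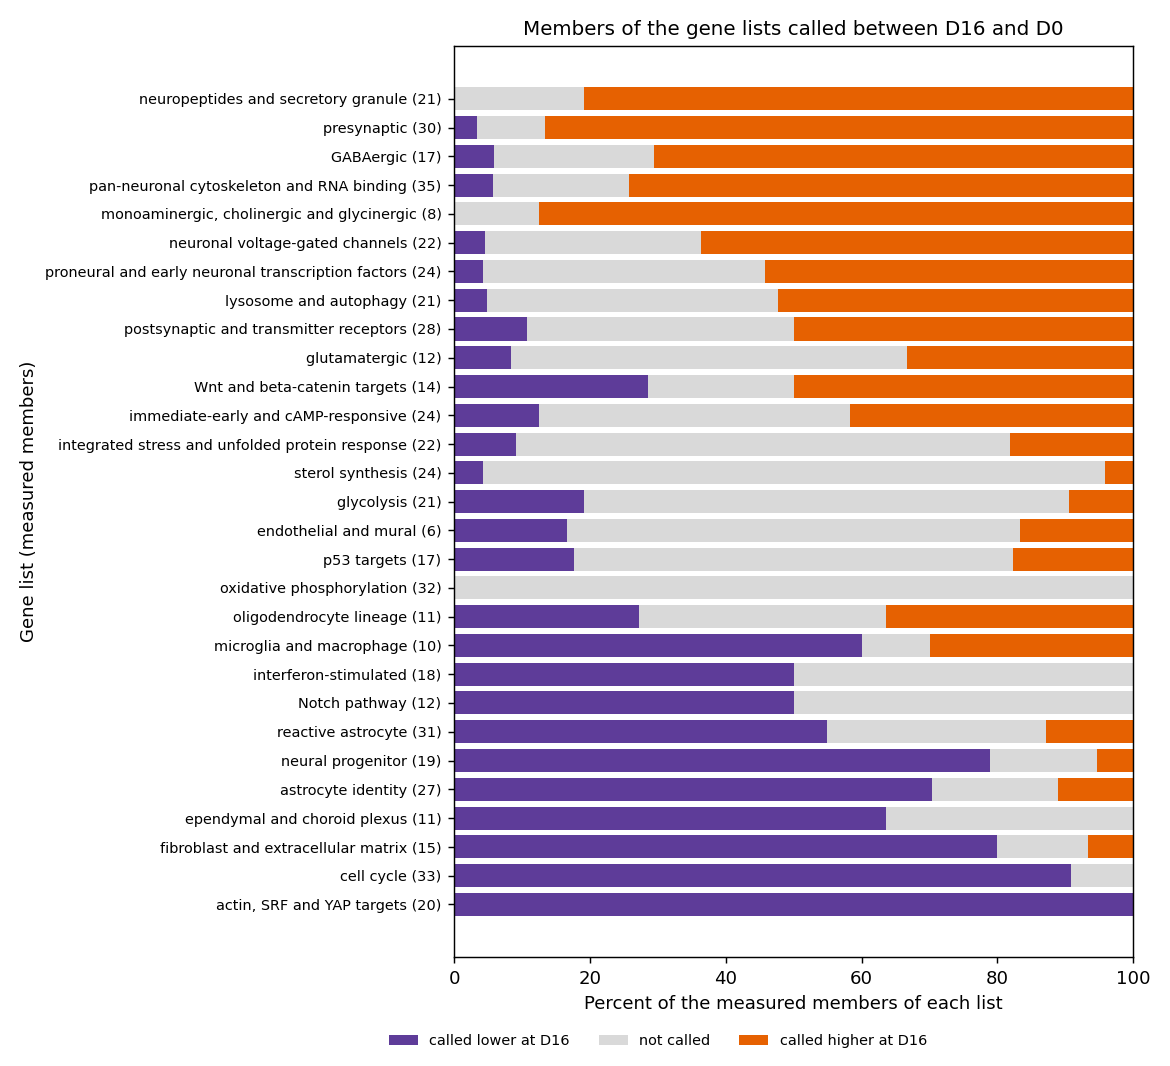
Members of the fixed gene lists called between D16 and astrocytes. Bars give the percent of the measured members of each list called lower, not called and called higher at D16, with the number of measured members in brackets.

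From D4 to D8, 70 genes rose and 211 fell. Vip rose from 11.7 ± 9.13 to 133 ± 37.2 FPKM (3.58 ± 0.69, adjusted p = 0.0084). It was followed by Ankrd34b (2.38 ± 0.32), the secreted Wnt-binding gene Sfrp2 (2.14 ± 0.29), Napb (2.09 ± 0.27), Resp18 (2.04 ± 0.37) and Tagln3 (1.85 ± 0.48). The falls were led by the cytokine gene Clcf1 (111 ± 69.2 to 6.81 ± 4.11 FPKM, -3.83 ± 0.45), S100a4 (-3.59 ± 0.36), and Gfap (398 ± 42.6 to 37.1 ± 5.22 FPKM, -3.39 ± 0.62). The mitotic genes Birc5 (-3.31 ± 0.31) and Ube2c (-3.15 ± 0.22, adjusted p = 2.1e-06) also fell. The call of Ctgf (-3.25 ± 0.82) was lost in 9 settings, among them the replicate block that follows the pairing of D4 and D8, and that of Tagln3 in 10 settings. Cell cycle genes were lower in 24 of 33 and not called in 9 (24 adjusted over the list alone), with Top2a from 10.1 to 0.432 FPKM. This list call held with an estimated correlation (adjusted p = 0.0337). Presynaptic genes were higher in 5 of 30 and pan-neuronal genes in 5 of 35, the rest not called, including Cplx1 (28.5 to 86.0 FPKM) and Stmn4 (36.1 to 124 FPKM; lists called, adjusted p = 0.174 and 0.106 with an estimated correlation). Both counts were 5 adjusted over the list alone. Neuropeptide genes were higher in 2 of 21, Pcsk2 and Chgb (a call lost in 9 settings), with 6 adjusted over the list alone, and reactive astrocyte genes lower in 4 of 31, with 8 adjusted over the list alone (lists called; both adjusted p = 0.174 with an estimated correlation). No lysosome gene of 21 was called (1 adjusted over the list alone), although their mean change of 0.46 gave a list call (adjusted p = 0.0649 with an estimated correlation). Without D4 replicate 2 the count of called genes went from 281 to 173.

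From D8 to D16 only 4 genes were called of 13983, and 1835 had an unadjusted p below 0.05. Hoxb9 rose from 15.7 ± 2.24 to 166 ± 137 FPKM (2.94 ± 0.44, adjusted p = 0.046), and the neuropeptide gene Adcyap1 from 3.65 ± 0.69 to 32.7 ± 27.6 FPKM (2.55 ± 0.40, adjusted p = 0.048). Cyp4f18, a cytochrome P450 gene, rose from 1.18 ± 0.227 to 5.35 ± 1.38 FPKM (1.52 ± 0.17, adjusted p = 0.0025). Stom, a membrane scaffold gene, fell from 68.9 ± 6.48 to 32.0 ± 4.04 FPKM (adjusted p = 0.046). The calls of Adcyap1 and Stom were lost in 11 other settings each, that of Hoxb9 in 9 and that of Cyp4f18 in 2. Gfap was at 37.1 and 4.22 FPKM and was not called (-3.72 ± 0.62, adjusted p = 0.057), and Vip at 133 and 697 FPKM was not called. The presynaptic list had no called gene of 30 and a mean change of 0.46, and the pan-neuronal list no called gene of 35 (2 higher adjusted over the list alone) and a mean change of 0.36 (lists called; adjusted p = 0.739 and 0.702 with an estimated correlation). D16 replicate 2 stood apart in sterol synthesis genes (mean log2 level 5.56 against 4.32 and 4.66), in Gal (59.5 against 304 and 320 FPKM) and in Vim (1610 against 712 and 687 FPKM). Without D16 replicate 1 the count of called genes was 73.

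Across the time course, 1533 genes rose and stayed higher from D4 to D16 and 1748 fell and stayed lower. Another 380 were called higher and 402 lower against D0 at D16 but not at D4 or D8. This tells when a cutoff against D0 was passed. Few of these changes can be placed after D8, since only 4 genes were called between D16 and D8. The 402 ran from 268 without D16 replicate 2 to 518 without D16 replicate 1. By a separate rule that can overlap with these groups, 115 genes rose by D4 or D8 and were called lower at D16 than at that time. Such a return, in either direction, need not reach the D0 level: Lcn2 was still called higher at D16 than at D0. Calca belonged to the transient group (3.34, 2791, 1054 and 166 FPKM at D0, D4, D8 and D16), as did Lcn2 (1.35, 451, 97.6 and 12.8 FPKM), Cryba2 and Calcb. Only 16 genes fell and then rose again, among them the membrane gene Myadm (66.9, 8.72, 10.3 and 19.4 FPKM), Speg, Lrfn4 and the neuromuscular adaptor gene Dok7 (11.1, 1.38, 3.69 and 10.5 FPKM). Genes absent from D0 included the Hox family: 28 of 39 reached 1 FPKM at D16, and their summed mean went from 0.478 at D0 to 60.4, 138 and 384 FPKM at D4, D8 and D16, with 0.630 FPKM in PN. The sums of the D16 libraries were 211, 324 and 616 FPKM in replicates 1, 2 and 3.

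Primary neurons differed from astrocytes in 5730 genes, 2391 higher and 3339 lower. The largest rises were Ly6h (0.481 ± 0.604 to 561 ± 80.6 FPKM, 8.63 ± 0.33), the microtubule regulator Stmn4 (575 ± 46.2 FPKM, 8.41 ± 0.27, adjusted p = 3.6e-12) and the tau gene Mapt (chromosome 11, start 104229409, end 104332090; 555 ± 60.9 FPKM, 8.27 ± 0.29). Others were the somatostatin gene Sst (456 ± 457 FPKM, 8.25 ± 0.56) and Nnat (2274 ± 325 FPKM). Acta2 (-8.80 ± 0.95), Tagln (-8.70 ± 0.94), S100a6 (2027 ± 480 to 6.44 ± 2.38 FPKM, -8.12 ± 0.35), S100a4 (-7.72 ± 0.36) and the muscle-type gene Cnn1 (-7.53 ± 0.50) were among the largest falls. Of 35 pan-neuronal genes 34 were higher and 1, Thy1, was lower, with Crmp1 from 2.20 to 688 FPKM. This list call also held with an estimated correlation (adjusted p = 0.0419). Presynaptic genes were higher in 29 of 30 with 1 not called, postsynaptic genes in 27 of 28 with 1 lower, and glutamatergic genes in 9 of 12 with 3 not called (lists called; adjusted p = 0.138, 0.154 and 0.0977 with an estimated correlation). The cortical factor Neurod6 (chromosome 6, start 55677818, end 55681263) went from a listed 0 to 236 ± 40.9 FPKM, and Grin1 from 0.216 to 61.5 FPKM.

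Sterol synthesis genes were higher in PN in 20 of 24 with 4 not called, with Hmgcs1 from 68.4 to 713 FPKM (list called; adjusted p = 0.403 with an estimated correlation). All 33 cell cycle genes and 19 of 20 actin and SRF target genes were lower, 1 of the latter not called, among them Ccnb2 (58.6 to 3.23 FPKM; lists called, adjusted p = 0.242 and 0.250 with an estimated correlation). Reactive astrocyte genes were lower in 21 of 31, 1 higher and 9 not called, and p53 targets in 12 of 17 with 5 not called (lists called; adjusted p = 0.250 and 0.287 with an estimated correlation). Timp1 went from 244 to 0.700 FPKM and Perp from 54.5 to 3.17 FPKM. All list counts were the same adjusted over the list alone. PN replicate 3 stood apart in contractile genes and Vim. Vim was at 847 FPKM against 177 and 98.3, Acta2 at 31.2 FPKM against 0.165 and 0.13, and the actin list at a mean log2 level of 4.16 against 2.19 and 2.20.

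D16 cells differed from primary neurons in 4840 genes, 2745 higher and 2095 lower at D16 (2394 and 2356 with quantile normalization). Vip (697 ± 545 against 1.66 ± 1.59 FPKM, 7.64 ± 0.69), the cell cycle inhibitor Cdkn2a (348 ± 149 against 0.870 ± 0.665 FPKM, 7.49 ± 0.30, adjusted p = 9.5e-11) and Cd40 (7.37 ± 0.47) led the genes higher at D16. Gpnmb (446 ± 386 against 1.53 ± 1.36 FPKM, 7.197 ± 0.67), Hoxb9 (6.93 ± 0.44) and Gal (6.84 ± 0.56) came next. The lowest were Neurod6 (0.0279 ± 0.0483 against 236 ± 40.9 FPKM, -7.83 ± 0.15, adjusted p = 2.9e-14), Bhlhe22 (-7.202 ± 0.24), Islr2 (-6.79 ± 0.38), Dcx (-6.66 ± 0.15, adjusted p = 2.0e-13), Caly (-6.51 ± 0.23) and Sparcl1 (-6.24 ± 0.63). Among general neuronal genes, Mapt was at 12.5 against 555 FPKM, the tubulin gene Tubb3 at 168 against 1660 FPKM, Map2 at 30.9 against 216 FPKM, and Rbfox3 at 5.58 against 50.1 FPKM, all lower at D16. Snap25 (172 against 195 FPKM, adjusted p = 0.73), Syn1, Nefl, Gad2 and Slc17a7 were not called. Rest and Slc32a1 (70.8 against 24.4 FPKM) were higher at D16, as was Gad1 (126 against 54.4 FPKM), whose call was lost in 7 settings.

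Pan-neuronal genes were lower at D16 than in PN in 22 of 35, 1 higher (Nefh) and 12 not called, and postsynaptic genes in 19 of 28, 1 higher and 8 not called (lists called; adjusted p = 0.207 and 0.471 with an estimated correlation). Nsg2 was at 34.0 against 952 FPKM and Gria1 at 0.626 against 62.1 FPKM. Glutamatergic genes were lower in 7 of 12, 1 higher and 4 not called, and presynaptic genes in 15 of 30, 2 higher and 13 not called, with Cplx2 at 10.4 against 148 FPKM (lists called; adjusted p = 0.207 and 0.587 with an estimated correlation). Sterol synthesis genes were lower in 15 of 24 with 9 not called, and cell cycle genes in 19 of 33, 2 higher and 12 not called (lists called; both adjusted p = 0.587 with an estimated correlation). Hmgcs1 was at 37.4 against 713 FPKM, and Ccnb1 at 0.141 against 8.23 FPKM. The PN libraries also held astrocyte transcripts, with Slc1a3 at 58.6 to 109.7 FPKM against 1.04 to 3.29 FPKM at D16. Astrocyte identity genes were lower at D16 in 11 of 27, 5 higher and 11 not called, and the list was not called (adjusted p = 0.0616). Lysosome genes were higher at D16 in 15 of 21 with 6 not called, with Ctsd at 1527 against 141 FPKM (list called; adjusted p = 0.207 with an estimated correlation). So were p53 targets in 11 of 17 with 6 not called, with Phlda3 at 251 against 24.1 FPKM (list called; adjusted p = 0.490 with an estimated correlation). Monoaminergic and cholinergic genes were higher in 6 of the 8 that passed the filter, of 16 listed, with 2 not called. Lmx1b was at 7.72 against 0.0167 FPKM (list called, adjusted p = 0.471 with an estimated correlation). Wnt targets were higher in 10 of 14, 2 lower and 2 not called, with Axin2 at 95.1 against 6.49 FPKM (list called; adjusted p = 0.587 with an estimated correlation). GABAergic genes split into 6 higher, 6 lower and 5 not called of 17: Vip was higher, and Sst (42.1 against 456 FPKM) and Calb2 lower. Counts adjusted over the list alone were the same for all 29 lists.

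Of the 2391 genes higher in PN than in D0, 1117 were also higher at D16 (46.7%; 397 expected if the calls were unrelated). Of the 3339 lower in PN, 1782 were also lower at D16 (53.4%; 625 expected). Another 218 genes were called in opposite directions, 145 of them higher at D16 and lower in PN. Both comparisons share the 3 D0 libraries, so part of the excess may come from them. The covariance of the 2 sets of changes was 1.49, against a mean of 0.0337 in 50 simulations of unchanged groups sharing D0. Noise in the shared libraries thus accounted for little of the covariance. The changes correlated at 0.637, and the simulated 0.502 is set by the sharing whatever the size of the noise. The simulations gave 0 shared calls, but few unchanged genes are called at all, so this does not measure the excess. With D16 and PN compared directly, 668 genes, Snap25 among them, were higher than D0 in both and not called between them. Another 1037 were higher at D16 than in both other groups, Vip, Gal and Hoxb9 among them, and 1251 were higher in PN than in both other groups, such as Neurod6 and Dcx.

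On a scale with D0 at 0% and PN at 100%, the 2391 genes higher in PN stood at 33.4 ± 3.58% at D4, 42.2 ± 5.72% at D8 and 49.2 ± 1.03% at D16 (mean ± SD of 3 libraries). The 3339 genes lower in PN stood at 38.2 ± 1.17%, 50.7 ± 2.98% and 57.1 ± 4.65%. By exact permutation of the libraries, neighbouring time points differed at p = 0.1, the smallest value 3 against 3 can give, except D8 against D4 in the genes higher in PN (p = 0.2). This test left the pairing of D4 and D8 out: each D8 library stood higher than the D4 library of its number (37.2 to 47.4%, 30.03 to 36.1% and 33.1 to 43.1%). By list, a measure added after the data were seen that took only the members called higher in PN (15 of 21 neuropeptide, 13 of 17 GABAergic and 14 of 24 proneural genes), neuropeptide genes stood at 116 ± 10.4% at D16, GABAergic at 83.2 ± 8.08%, and presynaptic at 73.0 ± 0.747%. Channels stood at 67.1 ± 2.04%, pan-neuronal at 55.8 ± 1.98%, proneural at 52.3 ± 2.11%, postsynaptic at 36.5 ± 1.93%, glutamatergic at 22.6 ± 3.37% and sterol synthesis at 13.2 ± 31.6%. The sterol libraries ran from -13.2 to 48.3%, and D16 replicate 2 had the highest level of the whole list (mean log2 level 5.56, against 4.32 and 4.66). Over all members, the mean log2 changes at D16 and in PN were 3.80 and 2.67 for neuropeptide genes and 2.865 and 2.755 for GABAergic genes. Snap25 was near the PN level at D16, and Mapt, Neurod6 and Dcx were far below it.

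**Figure D3:**
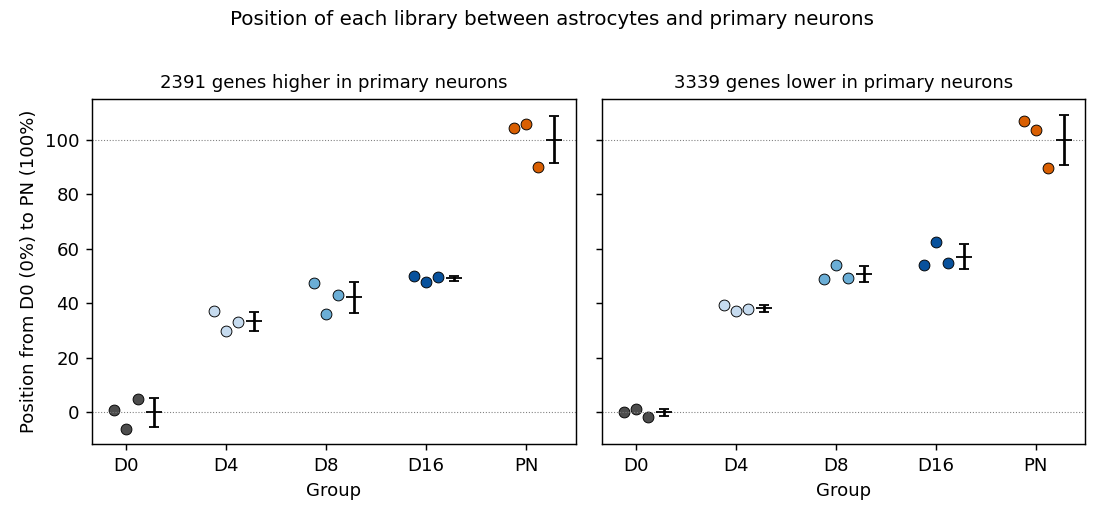
Position of the induced libraries between astrocytes and primary neurons. Points are single libraries, bars are mean and SD, and the scale runs from 0% (mean of D0) to 100% (mean of PN), for genes higher and genes lower in primary neurons than in astrocytes.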

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

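All tests of causes in the closing section were chosen after the results were seen, except the regrouping of libraries. The change from astrocytes was not the same at D4 and D16: 1007 genes were called between D16 and D4 in the same limma fit. Gfap moved most among the marker genes (log2 change from D4 to D16 of -7.12), with the glial genes Slc1a3 (-1.27), Gja1 (-2.03), Sox2 (-1.88) and Olig2 (-2.49) and the dividing-cell genes Mki67 (-2.22) and Top2a (-2.95) also lower. Neuronal genes that went on rising were Gad1 (2.87), Slc32a1 (2.42), Syt1 (1.47), Snap25 (1.43), Neurod1 (1.34), Syn1 (1.29) and Rbfox3 (1.25). Ptbp2 was also higher at D16 than at D4 (1.69), but after a fall: it stood at 36.6% of its D0 level at D4 and 138% at D16. Only 2 genes were called higher at D4 and lower at D16 against astrocytes, the transcription factor gene Maff (1.68 and -1.47) and the cytokine receptor gene Osmr (1.03 and -1.19).

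By list mean, and with most members of most lists not called, the lists lower at D16 than at D4 were cell cycle (mean log2 change -1.70, 24 of 33 called lower), actin and SRF targets (-1.42, 9 of 20) and reactive astrocyte (-1.10, 12 of 31). Neural progenitor (-0.94, 7 of 19) and astrocyte identity (-0.88, 8 of 27 lower and 1 higher) followed. Those higher by mean were presynaptic (1.07, 16 of 30 called higher), monoaminergic and cholinergic (0.95, 3 of 8), pan-neuronal (0.92, 14 of 35), neuropeptide (0.92, 7 of 21) and GABAergic (0.90, 4 of 17 higher and 1 lower) genes. Smaller means were those of channel (0.71, 6 of 22), postsynaptic (0.63, 6 of 28), lysosome (0.50, 1 of 21) and proneural (0.33, 5 of 24 called higher and 1 lower) genes. Sterol synthesis genes had a mean of 0.33 with 0 of 24 called, and D16 replicate 2 stood apart in them (mean log2 level 5.56, against 4.32 and 4.66 in the other D16 libraries and 4.35 to 4.66 at D4). None of these lists was called with an estimated correlation (lowest adjusted p = 0.133 with an estimated correlation).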

How the results depend on the processing

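The counts of called genes against astrocytes and between D16 and PN held in most settings. Leaving out single libraries gave 3770 to 3970 for D4, 4445 to 4582 for D8 and 4790 to 5107 for D16 against D0. It gave 5610 to 5942 for PN against D0 and 4768 to 5008 for D16 against PN. Among called named genes and called lists, none changed direction in the settings run on them. Lists were not run with libraries left out. The split into higher and lower genes depended on the pseudocount and the scaling. With a pseudocount of 0.1, D4 against D0 had 2501 higher and 2308 lower, against 1896 and 1991. D8 against D0 had 2738 and 2698, against 2164 and 2360. D16 against PN had 2745 higher and 2095 lower, 2779 and 2614 when rescaled, and 2394 and 2356 with quantile normalization. PN against D0 went from 2391 and 3339 to 2621 and 2851 with quantile normalization, and D8 against D4 from 70 and 211 to 46 and 244 when rescaled. Without a minimum on the change the counts were 7587, 8340, 8775 and 9067 for D4, D8, D16 and PN against D0, 8678 for D16 against PN and 467 for D8 against D4. The 4 genes called between D16 and D8 (Hoxb9, Adcyap1, Cyp4f18 and Stom) depended on the setting: 0 with a pseudocount of 0.1, 1 without a filter, 0 with the filter at 5, 2 when rescaled and 0 when only these groups were fitted. Leaving out single libraries gave 1 to 73, with 73 without D16 replicate 1, 11 without D8 replicate 1, and 1 without D8 replicate 2 or D8 replicate 3. D8 against D4 ran from 173 (without D4 replicate 2) to 338, and the genes that fell and rose again, 16 at first, ran from 10 (without D4 replicate 2) to 20. The cause was not tested.

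A pseudocount of 0.1 gave 26 genes that fell and rose again and 429 called in opposite directions at D16 and in PN, against 218. For the genes higher in PN it put D4, D8 and D16 at 41.9, 50.3 and 56.9% of the way from D0 to PN, and for the genes lower in PN at 31.3, 45.6 and 52.0%. Quantile normalization gave 29.2% for D4 and 46.7% for D16 in the genes higher in PN, and 41.7, 55.2 and 62.0% for D4, D8 and D16 in the genes lower in PN. Rescaling gave 40.1% for D4 and 56.6% for D8, and the filter at 5 gave 35.6% for D4 and 47.6% for D8, in the genes lower in PN, and 50.6% for D16 in the genes higher in PN. Leaving out libraries gave 47.2 to 50.6% for D16 in the genes higher in PN, and 36.4 to 39.9% for D4 and 51.9 to 59.1% for D16 in the genes lower in PN, where the low ends came from leaving out D16 replicate 2 and PN replicate 3 together.

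With a replicate block, which follows the pairing seen between D4 and D8, D8 against D4 had 300 called genes against 281, and D16 against D8 had 2. With a correlation estimated per list, the lists called were 0 for D4, 0 for D8, 0 for D16 and 1 for PN against D0 (pan-neuronal), 0 for D16 against PN, 1 for D8 against D4 (cell cycle) and 0 for D16 against D8. Of the called named genes, 4 of 138 between D16 and D0 (Arc, Chat, Nsdhl and Slc17a6) and 26 of 46 between D8 and D4 lost their call in at least 1 setting. Between D8 and D4 the calls of Tagln3 and Arc were lost in 10 settings each, those of Ctgf and Chgb in 9 and those of Snap25 and Grin1 in 8.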

Other observations

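Hox genes, which set position along the body axis, were near 0 in astrocytes and came up in all 4 clusters. Of 39 Hox genes, 28 reached 1 FPKM at D16, 7 of 11 in cluster A, 9 of 10 in cluster B, 7 of 9 in cluster C and 5 of 9 in cluster D. The 27 that passed the filter were called higher at D16, and 14 already at D4, but the induced libraries alone took them past the filter, so a call at D16 was nearly fixed by it. The cluster B genes reached a summed 276 ± 190 FPKM at D16 (125, 213 and 489 FPKM in replicates 1, 2 and 3), with Hoxb9 alone at 166 ± 137 FPKM, against 0.402 FPKM in PN. Other developmental factors listed below 0.1 FPKM at D0 also appeared at D16, such as Six2 (15.99 FPKM), Gata4 (11.3 FPKM), Pax1 (10.5 FPKM) and Alx1 (7.999 FPKM), none of which is a usual forebrain neuron gene.

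Background reads over silent genes would raise other silent genes as well, but 0 of 1493 silent chemosensory receptor genes reached 1 FPKM at D16, which argues against it. A wider loss of silencing at developmental regulators may contribute: 33.3% of the silent developmental transcription factors other than Hox (43 of 129) reached 1 FPKM at D16, against 4.93% of other silent genes and 6.98% of the same factors in PN. Of the 43, 8 are in the fixed neuronal lists, such as Neurod1 (9.17 FPKM), and without the listed genes it was 31.0% (35 of 113) against 1.77% in PN. Cells from a Hox-expressing body region cannot be told apart from it, since the forebrain factor Lhx2 kept 24.6% of its D0 level (82.8 to 20.4 FPKM), Emx2 36.7% and Otx2 56.3%. Whether such cells grew after D8 could not be decided. Cell cycle genes were lower than at D0 in 30 of 33 at D16 (Mki67 at 0.609% of D0). They showed no mean rise from D8 to D16 (log2 change -0.05), but were already low at D8 (Mki67 at 0.12 to 0.25 FPKM). A mean over all cells at this level cannot show growth of a part of them. Over this time the Hox sum went from 138 to 384 FPKM, with 211 to 616 FPKM in single D16 libraries. H3K27me3 profiling at the Hox clusters and single-cell sequencing at D4 could separate these explanations.

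Neuronal genes at D16 stood at uneven percents of the PN level, with Snap25 close to PN and Dcx and Neurod6 near 0. Neurons like the primary ones carried over in the cultures would bring all their abundant transcripts, so a share large enough for the median of 52 abundant pan-neuronal and presynaptic genes (34.0% of PN) would be a floor for each of them. Yet 4 of the 52 stood under 10% of the median in each D16 library, Dcx (0.240 ± 0.0778%), Sv2b (1.595 ± 0.350%), Mapt (2.245 ± 0.725%) and Dpysl3 (2.54 ± 0.618%), which argues against carry-over as the source of the median level. An earlier form of the test, a 10th percentile under 0.2 of the median in each library, was met with the D0 level subtracted (ratios of 0.0472, 0.00553 and 0.0256) and missed without (0.202, 0.210 and 0.156). A small share of such neurons, neurons of another kind and a change in the induced cells stay open, and lineage tracing of Gfap-expressing cells with staining for SNAP25 and DCX would test them.

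Y-linked genes were lowest in replicate 2 of D0, D4, D8 and D16, with Eif2s3y at 12.9, 14.7, 14.6 and 14.5 FPKM against 24.0 to 31.6 FPKM in the others. Depth or scaling is argued against, since 3586 genes of similar level differed by a median of at most -0.106 log2 in replicate 2. The same replicate number may mark the same starting culture. Chance alone makes the same number lowest in all 4 groups at 0.037. That value takes the groups as unrelated, and the pattern was picked after it was seen, so it gives no support. The choroid plexus gene Ttr was also highest in replicate 2 of D0 (64.6 FPKM), D4 (19.6 FPKM) and D8 (4.67 FPKM). Between D4 and D8 all same-number pairs correlated (0.329 to 0.454, against at most 0.114 for the others), so the numbers link those samples. Replicate 2 also had the highest relative depth in D0, D4, D8 and D16 (1.44, 1.62, 1.7 and 1.1). The link may therefore come from shared culture, depth or processing. For D0 and D16 a link cannot be told apart from chance. Genotyping the starting cultures would settle it.

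Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. All splits but the real one mix libraries of both groups, so any difference between the groups widens their spread and keeps their counts low. The low counts of the mixed splits therefore give no separate support. In each comparison only 1 split, the real one, called as many genes: 3887, 4524, 4935 and 5730 for D4, D8, D16 and PN against D0, with at most 0, 0, 0 and 2 in the others. It was 4840 for D16 against PN with at most 1, 281 for D8 against D4 with at most 0, and 4 for D16 against D8 with at most 1.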
